A study of Homo sapiens with 6 samples.

How the data were processed

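Gene expression was measured in the leukaemia line RS4;11 on 1-colour (Cy3) Agilent arrays, with 3 control cultures (0 nM) and 3 cultures kept for 48 h in 200 nM VE-465. Groups and replicate numbers were taken from the sample titles. Per the labels, the replicates are biological and come from 3 independent experiments.

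The arrays were read with Agilent Feature Extraction 10.5.1.1, per the file headers and the submitters' processing notes. Per the file headers, the deposited processed signal is a background-subtracted intensity on a linear scale, detrended within the array, in which low signals were replaced by surrogate values. No step between arrays had been applied to these values. The authors' series table holds a further set of intensity values per probe. These equal the geometric mean of the processed signals of a probe's unflagged spots within a tolerance of 0.1% for 100% of the values, the largest difference being 0.0218%, so they are linear and not scaled between arrays. Their column medians were 203, 301 and 148 for control replicates 1 to 3 and 97.1, 177 and 136 for VE-465 replicates 1 to 3.

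Each array has 62976 spots, of which 4259 are control spots and were left out. The remaining 58717 spots belong to 42405 probes. Spots marked as non-uniform or as population outliers, 246 to 288 per array, were left out, which left 2 probes without a spot. The main values are log2 of the processed signal minus log2 of the 75th percentile of that signal over the non-control spots of the array, averaged over the spots of a probe. Probes well above background on at least 3 of the 6 arrays were kept (35383 of those with a gene name), and each gene is represented by its probe with the highest mean over the 6 arrays. Of 135 named genes 41 had several kept probes, and for 12 of these the probes differed in the sign of the fold change.

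Gene names were updated through the RefSeq gene table of GRCh38.p14, used for names and gene order only. It matched 28815 probes to a symbol: 25771 by accession, 2207 by the symbol in the files, 502 by an older symbol and 335 by the gene number in a LOC name. The match by gene number was added after the calls had been seen, when a called LOC entry was found to have a current symbol. 11694 further probes keep the name of the files and are counted as transcripts without a symbol, and 1896 probes without a gene name were not part of the tests by gene. Probe positions are those of the files, on hg19. CDKN1A was read by a probe on chromosome 6 from 36652178 to 36652237, EDA2R by one on chromosome X from 65815490 to 65815549, TNFRSF10B by one on chromosome 8 from 22877776 to 22877835 and AURKA by one on chromosome 20 from 54945120 to 54945179. The sources used here do not state which exon or UTR a probe lies in.

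VE-465 was compared with control in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 2 groups, no further term), and p-values were adjusted by Benjamini-Hochberg over the 27893 genes, with a threshold of 0.05. A second count required a change of at least 2-fold as well. Fold changes are VE-465 over control with 95% intervals from the moderated standard error. The number of arrays, 3 per group, limits the precision. The median residual SD was 0.209 on the log2 scale.

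The gene lists, 28 with 769 distinct genes, and the rule for named genes were fixed before the data were examined. Lists were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation beside it, and with fry, each adjusted over the 28 lists. The position of a list's median was also set against 10000 random lists matched on mean signal. Genes were named if they were among the 12 highest or 12 lowest fold changes of called genes well above background on all 6 arrays, with groups that do not overlap and a proper symbol in the files. Named too were a fixed set of genes of the drug's targets, cell cycle, p53 pathway and fusion biology, up to 4 members of each list with the smallest p, and up to 3 genes per direction measured in 1 group only. No gene was lower among the calls, so the rule named none there. Some genes that the rule names are not reported here.

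On simulated data with the spread of the real genes (27893 genes, 50 changed at each of 4 sizes), the test recovered 4% of changes of 0.5 on the log2 scale, 34% of changes of 1, 82% of changes of 1.5 and 82% of changes of 2, with 5 false calls. The simulated noise was independent between genes and arrays and held no slide difference, so these rates may not hold for the real arrays. A list shifted in simulated data without correlation between genes was called and no other list was.

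Alternatives covered background correction (normexp with an offset of 50), normalization (quantile, median, the authors' values), the filter on dim probes, the choice of probe, the variance prior, the replicate number and the slide as blocks, the slide that holds both groups, a plain unmoderated 2-sample test and leaving out each array in turn. Cyclic loess normalization and gene names without matching gene numbers were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python.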

Results

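RS4;11 is an established human B-cell precursor acute lymphoblastic leukaemia line whose t(4;11) translocation joins KMT2A to AFF1. VE-465 is a small-molecule inhibitor of the Aurora kinases, which act in spindle assembly, chromosome segregation and cytokinesis. Cells of 3 independent experiments were kept for 48 h with 200 nM VE-465 or without it, and the total RNA of each culture was hybridised to an array of its own, giving 3 control and 3 VE-465 arrays. The 75th percentile of the processed signal ran from 705 on the array of VE-465 replicate 1 to 2136 on that of control replicate 2. Between 82.0% and 89.5% of the probes of an array were well above background, and no spot was saturated. A total of 27893 genes and transcripts were tested, of which 18678 carry a current gene symbol.

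The 6 arrays lay on 2 slides. Slide 1 held the 3 control arrays and VE-465 replicate 3, and slide 2 held VE-465 replicates 1 and 2 alone. The first principal component, with 40.0% of the variance, set slide 2 apart from slide 1: VE-465 replicates 1 and 2 had scores of 42.85 and 41.22, and VE-465 replicate 3, at -18.67, lay among the controls, which ran from -29.5 to -11.01. The comparison of VE-465 with control within 1 slide therefore rests on a single treated array.

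**Figure D1:**
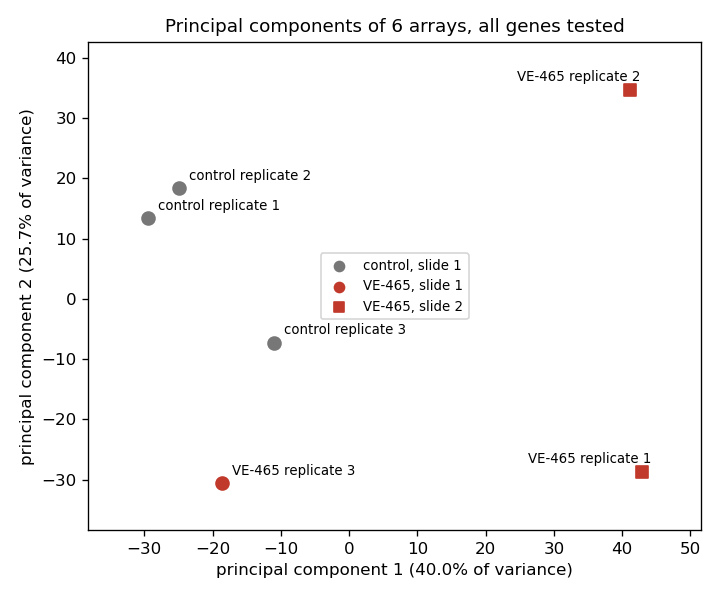
Scores of the 6 arrays on principal components 1 (x axis) and 2 (y axis), computed from log2 signal scaled to the 75th percentile over 27893 genes, with 1 point per array, grey for control, red for VE-465, circles for slide 1 and squares for slide 2. VE-465 replicates 1 and 2, both on slide 2, have scores of 42.85 and 41.22 on component 1, and the 4 arrays of slide 1 lie below 0.

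The comparison addressed which genes change their expression in these leukaemia cells after 48 h of Aurora kinase inhibition. Target genes of the transcription factor p53 were higher in the treated cells. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 3.28-fold (95% interval 2.37 to 4.54, limma adjusted p = 0.0367). The receptor genes EDA2R and TNFRSF10B, the latter a death receptor for TRAIL, rose 3.47-fold (2.78 to 4.34, adjusted p = 0.00966) and 3.36-fold (2.54 to 4.46, adjusted p = 0.0195). PHLDA3, which encodes an inhibitor of AKT, rose 2.68-fold (2.06 to 3.50), and ZMAT3, which encodes an RNA-binding zinc finger protein, rose 2.65-fold (2.17 to 3.24). Each of these genes was higher on all 3 VE-465 arrays than on any control array.

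Of the 38 genes on the fixed p53 target list 36 were tested, and 35 of them had a log2 fold change above 0. 5 rose at an adjusted p under 0.05 over all genes, and 29 rose and none fell when adjusted over the list alone. MDM2, the ubiquitin ligase that restrains p53, had a log2 fold change of 1.04 ± 0.15 (SE, n = 3 per group), past the threshold over the list alone (adjusted p = 0.000643) and not over all genes (limma adjusted p = 0.0848). BBC3, which encodes the proapoptotic protein PUMA, and BAX also rose only over the list alone, by 0.86 ± 0.14 and 1.04 ± 0.22 on the log2 scale. BAX had 2 kept probes, and the dimmer one gave 0.16. The list median was 0.84 on the log2 scale, or 1.79-fold, above every one of 10000 random lists matched on mean signal. The list lay higher than other genes by camera with its preset correlation (adjusted p = 3.74e-41). With an estimated correlation the adjusted p = 0.0736, which does not pass, and fry, which tests whether the list's genes move one way, gave an adjusted p = 0.00686. Against the control mean, the list medians on the arrays of VE-465 replicates 1, 2 and 3 were 0.78, 0.82 and 0.77, so that the single treated array on the slide of the controls had a median close to those of the others.

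**Figure D2:**
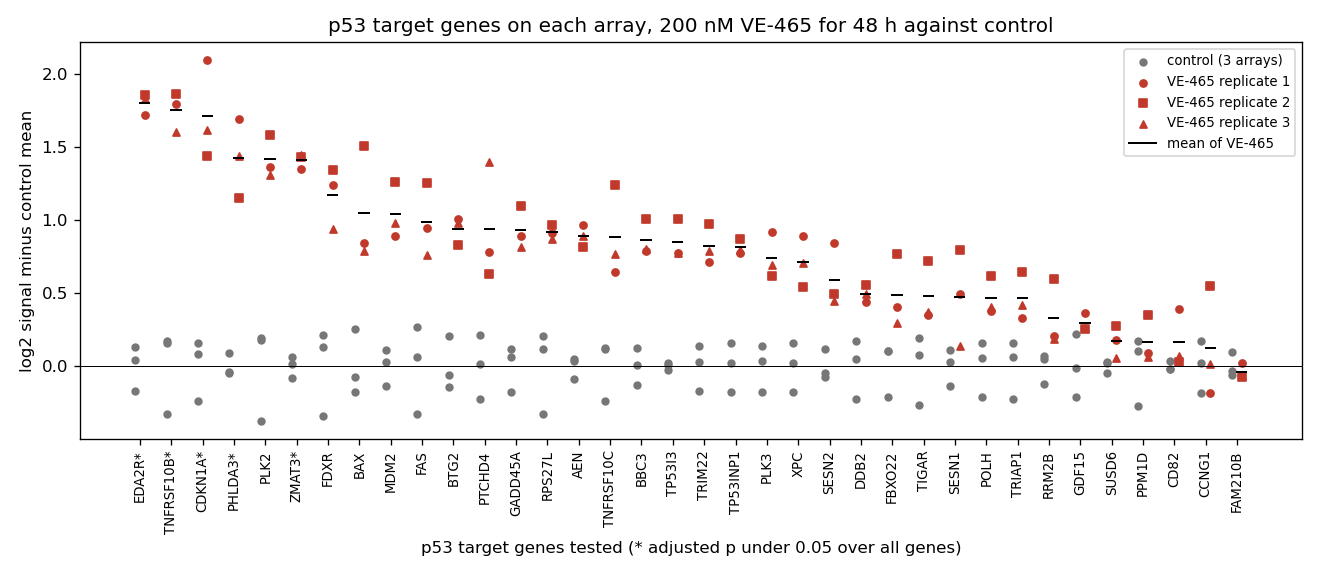
Log2 signal minus the mean of the 3 controls (y axis) for the 36 tested p53 target genes (x axis, ordered by fold change), with grey points for the 3 control arrays, red points for the 3 VE-465 arrays and a bar for the mean of VE-465. The 5 genes with an asterisk passed an adjusted p of 0.05 over all genes, and 35 of the 36 bars lie above 0.

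Across all genes and transcripts 26 rose at an adjusted p under 0.05 and 0 fell (limma). All 26 rises were at least 2-fold, from 1.19 to 2.40 on the log2 scale. Some of the 26 lie side by side and may read the same transcript, so 26 is not a count of separate genes. The smallest adjusted p of a gene with a lower mean in VE-465 was 0.153. At an unadjusted p under 0.05 there were 978 genes higher and 1118 lower, 2096 in all against 1395 that chance gives, and a plain unmoderated 2-sample test called none in either direction after adjustment. The groups did not overlap for 12.2% of the genes, where 3 against 3 gives 10% by chance. The p53 target list contributed 5 of the 26 genes, where 0.0336 would be drawn by chance (Fisher's exact test over genes, one-sided p = 1.73e-10; genes are not independent of each other).

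Outside the p53 list, further genes met the naming rule. PRDM1, which encodes the plasma cell repressor BLIMP-1, rose 3.57-fold (2.55 to 5.00, adjusted p = 0.0352). APOBEC3H, a cytidine deaminase gene, rose 3.41-fold, and MGAT3, a glycosyltransferase gene, rose 3.38-fold. CALML6, which encodes a calmodulin-like protein, and SIPA1L2, which encodes a GTPase-activating protein, rose 3.91-fold and 3.83-fold. ACTA2, the smooth muscle actin gene, rose 3.20-fold (2.50 to 4.10, adjusted p = 0.0127) and was the single call among the 13 tested stromal and epithelial markers. Another 4 called genes with a symbol, named after their values were seen, were PURPL at 5.28-fold, MTUS2 at 2.49-fold, PGF at 2.42-fold and CYSRT1 at 2.28-fold. PURPL is a long noncoding RNA described as a p53-induced regulator of p53 levels. The remaining 10 called features have no current symbol.

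The number of calls depended on single arrays, each of which is 1 of 3 in its group. Without control replicate 1, 2 or 3, or without VE-465 replicate 1, the count fell to 0. Without VE-465 replicate 2 it was 15, and without VE-465 replicate 3 it was 1126 genes, 139 higher and 987 lower. With the slide as a fixed block 32 genes passed, 20 higher and 12 lower, and within slide 1 alone 20 passed, 15 higher and 5 lower, with 8 of the 26 among the calls in each case. The fold changes of several called genes moved less than the count: over the 23 alternatives EDA2R ran from 1.56 to 1.86 on the log2 scale, TNFRSF10B from 1.49 to 1.84, ACTA2 from 1.57 to 1.75 and ZMAT3 from 1.24 to 1.44. Those of PRDM1 and SIPA1L2 ran more widely, from 0.81 to 1.96 and from 0.83 to 2.03. The slide term itself passed for 381 genes. As slide 2 holds no control, that term sets VE-465 replicates 1 and 2 against replicate 3. It cannot tell a slide effect from a difference between the experiments. CDKN1A had a log2 fold change of 1.61 within slide 1 and EDA2R one of 1.82, beside 1.71 and 1.80 over all arrays.

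The genes of the Aurora kinases did not pass the test. AURKA had a log2 fold change of -0.10 ± 0.12, AURKB, the catalytic subunit of the chromosomal passenger complex, one of -0.22 ± 0.17, and AURKC one of -0.04 ± 0.19 (SE, n = 3 per group, limma adjusted p = 0.834, 0.739 and 0.965). None of the 13 tested members of the list of Aurora kinases and their partners was called, and the list as a whole was not shifted (camera adjusted p = 0.89). The mitotic regulators CCNB1, at -0.02 ± 0.15, and PLK1, at 0.47 ± 0.37, were not called either. For the median gene the 95% interval of the fold change spanned a factor of 1.31 either way.

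Genes of DNA replication and the G1/S transition lay lower as a group by camera with its preset correlation (adjusted p = 1.73e-11), and did not pass with an estimated correlation (adjusted p = 0.208). No member passed the test on its own by limma, over all genes or adjusted over the list alone, nor by the plain unmoderated test. At an unadjusted p under 0.05, 16 members were lower. Of 43 tested members, 42 had a log2 fold change under 0, with a median of -0.29 and array medians of -0.32, -0.22 and -0.30. Examples are CDC45, a helicase component, at -0.51 ± 0.17, PRIM1, the primase subunit, at -0.46 ± 0.16 and GINS1 at -0.51 ± 0.17. The spindle checkpoint and kinetochore list also lay lower, with 29 of 32 members under 0 and a median of -0.24 (camera adjusted p = 1.54e-06, and adjusted p = 0.547 with an estimated correlation). CENPU, a centromere protein gene, had a value of -0.58 ± 0.14, and SPC25, part of the NDC80 complex, one of -0.58 ± 0.17. The medians of this list were -0.34, -0.08 and -0.31 on the arrays of VE-465 replicates 1, 2 and 3.

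Of the other lists that lay lower by camera, cholesterol synthesis and uptake had 22 of 24 members under 0 and a median of -0.23 (adjusted p = 0.000163, and adjusted p = 0.547 with an estimated correlation). INSIG1, which encodes a regulator of sterol synthesis, stood at -0.54 ± 0.19 and was not called. DNA repair and damage signalling had 22 of 26 members under 0 (median -0.17, adjusted p = 0.000745), and mitotic entry and exit had 34 of 38 under 0 (median -0.18, adjusted p = 0.00276). With an estimated correlation the adjusted p was 0.547 for the repair list and for the mitotic list. The call for the cholesterol list ended without control replicate 3 (camera adjusted p = 0.243), and those for repair and for mitotic entry ended without VE-465 replicate 3 (adjusted p = 0.148 and 0.409). Over the alternatives the camera adjusted p of these lists had a minimum of 2.44e-09, 1.22e-07 and 3.12e-09, with the values just given as the maximum.

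Of 29 tested replication-dependent histone genes 22 had a log2 fold change above 0, with a list median of 0.21 (camera adjusted p = 2.4e-06, and adjusted p = 0.569 with an estimated correlation). H1-2 had a value of 0.65 ± 0.21 and H1-3 one of 0.57 ± 0.17, neither past the threshold. On the arrays of VE-465 replicates 1, 2 and 3 the list medians were 0.41, -0.0017 and 0.23. The list medians of the control arrays spanned 0.45 on the log2 scale, more than the difference of 0.21 between the group means of these medians.

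Besides these, 3 lists lay higher by camera, namely the KMT2A fusion target genes (20 of 24 above 0, median 0.15, adjusted p = 0.00103), the immediate early genes (20 of 24 above 0, median 0.15, adjusted p = 0.00276) and the ribosomal proteins (29 of 34 above 0, median 0.13, adjusted p = 0.000745). With an estimated correlation the adjusted p was 0.547, 0.547 and 0.693. On the arrays of VE-465 replicates 1, 2 and 3 the medians were 0.09, 0.20 and 0.07 for the fusion targets, 0.23, -0.03 and 0.11 for the immediate early genes and 0.15, 0.0099 and 0.18 for the ribosomal proteins, so that the immediate early genes had a median below 0 on the array of VE-465 replicate 2. Within slide 1 the medians of the KMT2A fusion targets and immediate early genes were 0.07 and 0.11, and neither list passed there (camera adjusted p = 0.284 and 0.287). The call for the fusion targets also ended without VE-465 replicate 2 (adjusted p = 0.0953), that for the immediate early genes without VE-465 replicate 1 (adjusted p = 0.0601) and that for the ribosomal proteins without control replicate 2 (adjusted p = 0.511). All 3 calls ended with normexp and the 75th percentile, where the medians were 0.05 for the fusion targets, 0.22 for the immediate early genes and 0.07 for the ribosomal proteins. Over the alternatives the adjusted p ran from 1.18e-05 to 0.871, from 0.000424 to 0.294 and from 1.66e-06 to 0.711. The median of the ribosomal proteins was -0.07 after quantile normalization and -0.05 after normexp and quantile normalization. Among the fusion targets, FLT3, a receptor tyrosine kinase gene, had a value of 0.47 ± 0.16 (limma adjusted p = 0.646), HOXA9 one of 0.02 ± 0.15 and MEIS1 one of -0.02 ± 0.13. KMT2A stood at 0.15 ± 0.13 and AFF1 at -0.10 ± 0.13, and other probes of AFF1 and MEIS1 gave the opposite sign.

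In all, 10 of the 28 lists passed with the preset correlation, 5 higher and 5 lower, and 0 passed with an estimated correlation. By fry 1 list passed in direction, that of the p53 targets, and 3 passed in either direction. 18 lists did not pass camera, among them the B-lineage genes (15 of 31 above 0, median -0.03), the apoptosis regulators (18 of 29 above 0, median 0.06, adjusted p = 0.0524) and the interferon response (18 of 38 above 0). The apoptosis regulators passed with the mean of all probes of a gene (adjusted p = 0.00251), without control replicate 1 (adjusted p = 0.043) and without VE-465 replicate 1 or 3 (adjusted p = 0.0213 and 0.015), with a range over the alternatives from 0.00251 to 0.952. Adjusted over the list alone, 2 apoptosis regulators (BAX and BBC3) and 1 interferon response gene (TRIM22) rose, each of them also on the p53 list. The oxidative phosphorylation list had 21 of 26 members under 0 and a median of -0.10. It did not pass over all arrays (camera adjusted p = 0.171, and 0.746 with an estimated correlation). Camera passed it under 4 alternatives, among them normexp and the 75th percentile (adjusted p = 1.24e-05) and without VE-465 replicate 2 (adjusted p = 0.0139). Within slide 1, which has a single VE-465 array, its median was -0.16. BCL2 and MCL1, which encode antiapoptotic proteins, both stood at -0.05, with a standard error of 0.15 and 0.13, and MYC at 0.04 ± 0.15, none of them called. Markers of monocytes and granulocytes, of T and NK cells and of erythroid cells and megakaryocytes had list medians of -0.01, 0.06 and -0.04. The sign of the median, the mean or a test differed within 3 lists, those of B-lineage genes, T and NK cell markers and interferon response.

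**Figure D3:**
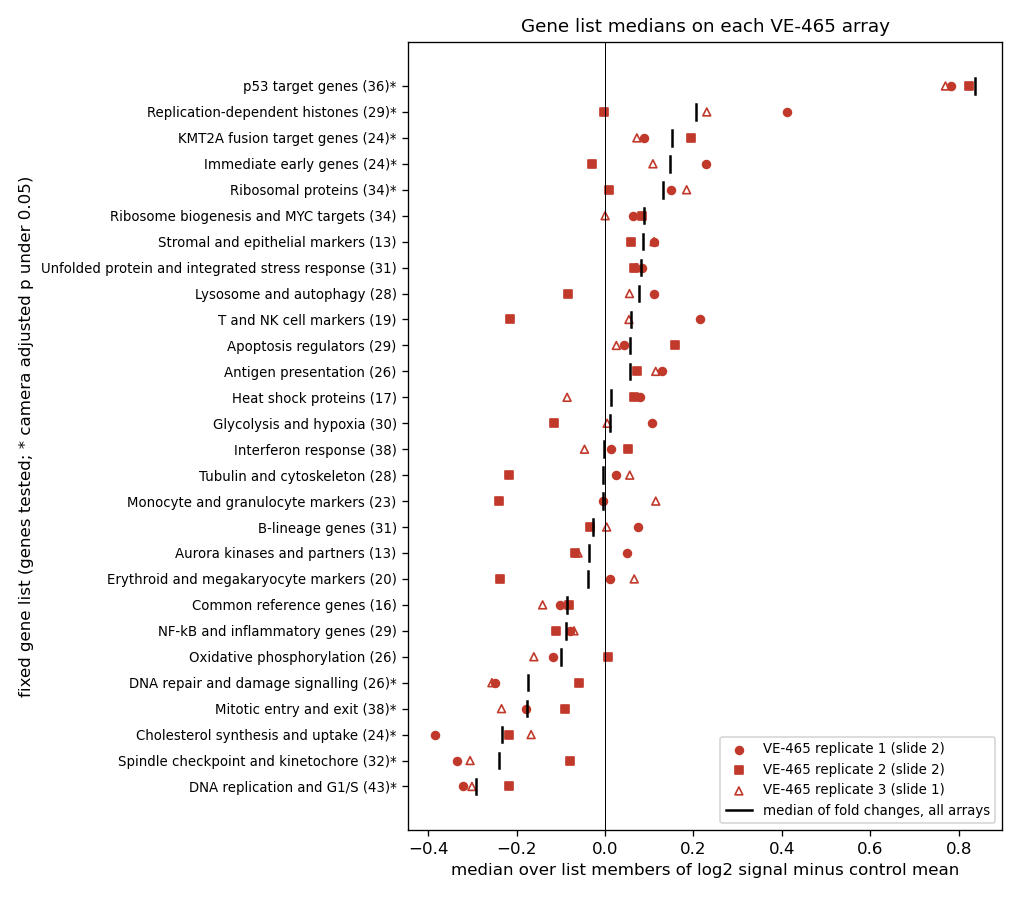
Median over the members of each of the 28 fixed gene lists (y axis, with the number of genes tested) of log2 signal minus the control mean (x axis), with 1 red symbol per VE-465 array, open for the array on slide 1, and a black bar for the median of the fold changes over all arrays. The p53 target list has array medians of 0.78, 0.82 and 0.77, and the 10 lists with an asterisk passed camera with its preset correlation.

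Some transcripts were measured well above background in 1 group only. 5 genes were so on all 3 VE-465 arrays and on no control array, and 24 on all 3 control arrays and on no VE-465 array. The share of probes well above background was 88.9%, 89.5% and 82.8% for control replicates 1 to 3. For VE-465 replicates 1 to 3 it was 82.0%, 87.3% and 83.9%. As the arrays differ in this share, the counts cannot be read as gains and losses with the drug. OR52N4, an olfactory receptor gene, was higher in VE-465 with a bound of 2.48-fold (limma adjusted p = 0.0582). EPHA7, an ephrin receptor gene, was lower with a bound of 2.48-fold, KCNT2 with one of 1.93-fold and FAM87B with one of 1.87-fold. None of these 3 passed the test (adjusted p = 0.58, 0.646 and 0.638). Within slide 1 the log2 differences of EPHA7, KCNT2 and FAM87B were -0.94, -0.31 and -0.34, smaller than these bounds. The groups overlapped for KCNT2, and with normexp and the 75th percentile KCNT2 and FAM87B had the opposite sign (0.26 and 0.11). EPHA7 had a log2 difference of only -0.06, and OR52N4 one of 0.33, under the alternative with the smallest change of each. Both are smaller than the bounds of 2.48-fold, so these bounds do not hold under every alternative. Each bound sets the mean of the brighter group against the lowest signal that counted as well above background on each array of the dimmer group, or the probe's own signal where that was higher.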

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

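2 of the alternatives, cyclic loess and gene names without matching gene numbers, were chosen after seeing the data, and gave 31 and 26 genes and 10 lists each. The 26 genes became 53 with normexp and quantile normalization, 54 with normexp and the 75th percentile, 45 with median scaling, 43 with probes well above background on all 6 arrays, 17 without a filter on dim probes, 41 with each probe tested on its own, 72 with a trended and robust variance prior and 0 with the plain 2-sample test, all of them higher in VE-465. The count of at least 2-fold changes, 26, became 41 with normexp and the 75th percentile, 44 with median scaling, 41 with probes above background on all arrays, 17 without the filter, 41 by probe, 54 with the trended prior and 0 with the plain test. Leaving out 1 array gave 0 to 1126 genes and 0 to 646 at least 2-fold changes. The ribosomal protein list turned to a median of -0.0547 with normexp and quantile normalization and to -0.0739 with quantile normalization. The causes were not tested, except for the ribosomal protein list, where the test could not decide, and the case without VE-465 replicate 3.

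The replicate block gave 25 genes, all at least 2-fold, 14 of them among the 26, and 10 lists. Whether equal replicate numbers mark the same experiment stays open. Deviations from the group means of equally numbered arrays correlated at -0.079, 0.202 and 0.048, and control replicates 1 and 3 correlated best with another number. With 3 arrays per group and the VE-465 arrays split over 2 slides, these correlations cannot exclude pairing. Beside 5 lists higher and 5 lower, there were 2 and 7 after normexp and the 75th percentile and 8 and 3 without VE-465 replicate 3. The list count stayed at 9 to 12 under the 20 alternatives that gave one. Of the 10 lists 4, the p53 targets, DNA replication, the kinetochore list and the histones, passed under each of these with the preset correlation, none of the 4 passed with an estimated correlation (adjusted p = 0.0736, 0.208, 0.547 and 0.569), and the p53 list median ran from 0.73 to 0.87. The 12 named genes called over all genes kept their direction under all 23 alternatives, and each lost its call under at least 6 of them. MDM2 passed under 5 (adjusted p from 0.0167 to 0.46). No list test was run with the slide as a random block, where 35 genes passed, nor for single probes or the plain test.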

Other observations

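The test of neighbouring genes, the comparison of the p53 list between VE-465 arrays, the matched random lists and the splits for gene counts were chosen after the results they bear on had been seen, and the features named next were chosen after their values were seen. The comparisons with a held-out control and the splits for gene lists had their predictions written before their outcomes were seen, though after the count without VE-465 replicate 3 was known. 2 further checks were taken out of the weighing after their outcomes were seen, to keep it to 3 patterns: the control arrays' medians of the histone list spanned 0.45 against a difference of 0.21 between groups, and the p53 list had a median of 0.77 within slide 1. Of the 26 features that rose with VE-465, 10 have no current symbol. 4 of them are reverse-strand long intergenic transcripts of a region on chromosome 1 (hg19, 9206863 to 9241488) between the genes GPR157 and H6PD, with rises of 3.63-fold to 4.83-fold. The region held 7 tested reverse-strand features, and 4 forward-strand ones of which 0 were called (limma). In the RefSeq order of GRCh38.p14 the genes between GPR157 and H6PD are MIR34AHG, MIR34A, known as a p53-regulated microRNA gene, and LNCTAM34A. 2 further called features lie beside PURPL on chromosome 5, with probes 0.5 kb and 1.1 kb from its probe, and rose 4.54-fold and 2.81-fold. Another, 64.3 kb from the probe of ZMAT3 on chromosome 3, rose 4.33-fold, and one 201.6 kb from the probe of PTCHD4 on chromosome 6 rose 4.10-fold. The last 2 have no such neighbour. One on chromosome 2, 85.7 kb from the probe of IKZF2, rose 3.42-fold. The other, on chromosome 1, was well above background on the 3 VE-465 arrays alone. Its measured signal was 4.69-fold higher (95% interval 3.43 to 6.41). The nearest probes of a listed p53 target lay 189476.5 kb and 58241.1 kb away. 2 of the 10 lay within 250 kb of a probe of a listed p53 target, against 79 of 9100 other transcripts without a symbol (Fisher's exact test, one-sided p = 0.00336). The distance was set after the features had been seen, so this p is no evidence for transcription shared with neighbouring p53 targets, which stays an open hypothesis. The 4 features of chromosome 1 are not independent of each other, and the 2 beside PURPL may not be independent of PURPL.

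Leaving out VE-465 replicate 3, the one treated array on the slide of the controls, raised the calls from 26 to 1126, with 139 genes higher and 987 lower. A difference between the slides as the whole cause is argued against for the rises: the 139 genes with the smallest p for a rise in VE-465 replicates 1 and 2 over 2 controls were also higher in replicate 3 than in the control held out, by a median of at least 0.80 on the log2 scale for each of the 3 choices of control. Without the 26 genes the median was at least 0.69. Whether replicate 3 responded less stays open. The median of the p53 list there lay only 0.0136 under the lower of the medians of replicates 1 and 2, but the median rise of the 139 genes was 1.33, 1.32 and 1.12 in replicates 1 and 2, larger than in replicate 3 by 0.54, 0.42 and 0.02. The rise in replicates 1 and 2 is over the 2 controls used to choose the genes, and that in replicate 3 is over the held-out control. Differences between the controls therefore enter these values. Selection of the genes on replicates 1 and 2 and on these 2 controls gives a difference of this direction as well, and its size was not estimated. For the falls the slide and a response particular to 2 of the experiments cannot be told apart: the 987 genes chosen in the same way for a fall were not lower in replicate 3 (the held-out control minus replicate 3 had medians of -0.29 to -0.02), but slide 2 holds no control array. Of the 987 genes called lower without replicate 3, 84.5% lay below the median gene in mean signal, against 48.9% of the 139 called higher.

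The ribosomal protein list lay higher by camera with its preset correlation, with a median of 0.13. It did not pass camera with an estimated correlation (adjusted p = 0.693). A scaling difference that depends on spot brightness is a candidate explanation: the other genes among the 100 brightest had a median of 0.22. The list median stood at percentile 5.4 of random lists matched on mean signal. For so bright a list this percentile cannot decide the question. Draws past the top of the signal ranking were set to the brightest gene, and the list's own genes could be drawn. After quantile normalization the list median was -0.07, while after cyclic loess it was 0.08. Only the listed genes were left out of the 100 brightest, so ribosomal protein genes outside the list could be among the others. Whether ribosomal protein genes responded to VE-465 beyond equally bright genes therefore cannot be told from these values. The 2790 brightest genes had a median of -0.0184, which argues against a rise shared by all bright genes. A rise limited to genes such as the 100 brightest, through scaling or as a response, stays open.

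The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 26 genes, all at least 2-fold, and the highest of the other splits gave 0, so that 1 of the 10 splits reached each of these counts. Every other split mixes treated and control arrays in both groups, so a drug effect widens the residual spread there and lowers such counts. For the gene lists the real split gave 10 and the highest other split 11, and 4 of the 10 splits gave as many. The split with 11 set control replicate 1 and VE-465 replicates 1 and 2, which include both arrays of slide 2, against the rest. With the slide as a block 9 lists passed. The p53 list had a camera adjusted p of 3.74e-41 in the real split and 1.09e-08 at the smallest in another. For the DNA replication list these were 1.73e-11 and 3.59e-07. With the real split included, the p53 list passed in 7 of the 10 splits and the DNA replication list in 4. In every other split 1 side holds more treated arrays than the other, so part of a drug effect remains between the sides. For the lists these splits therefore do not show what chance alone gives.

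Among 1577 probes without a gene name that were well above background on at least 3 arrays, 0 passed the threshold (limma), with 104 at an unadjusted p under 0.05.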
